A study of Mus musculus with 8 samples.

How the data were processed

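Total RNA from mouse oocytes was sequenced in 8 libraries, each made from 5 to 10 oocytes. Per the series title, mice lacking BAF250a through Gdf9-cre, a recombinase expressed in growing oocytes, were compared with control mice at the germinal vesicle (GV) stage and in metaphase of the second meiotic division (MII). BAF250a is the protein encoded by Arid1a, the DNA-binding subunit of the BAF (SWI/SNF) chromatin remodelling complex. Per the labels, the strain was C57BL/6, the genotypes were wildtype and BAF250aGKO, and there were 2 libraries in each of 4 groups: control GV, knockout GV, control MII and knockout MII. The labels do not say that replicates came from separate animals, so the p-values measure only the spread between these libraries. Libraries were made with a standard Illumina protocol, per the labels.

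The deposited values were counts per Ensembl gene, given by the authors in 1 table with 54838 gene entries and 5 HTSeq summary entries that name no gene. Per the submitters' processing notes, reads were aligned to mm10 with Bowtie2, counted with HTSeq and analysed with edgeR. Tool versions, the annotation release, the strand setting, trimming and filters are not given in the sources used here. The counts were checked to be whole numbers with a different total in each column, so no normalization precedes the steps below. Per the file headers, 2 columns carry the same name, that of the second control MII library. Both were used as control MII, as libraries a and b in arbitrary order, and no replicate number was used for them. All value columns were used, leaving 0 unused. The summary entries stayed out of library sizes and held 22% to 35.13% of the reads of a library. The distance between replicate columns, as a chi-square per degree of freedom between 50.5 and 111, ruled out duplicated columns.

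Gene symbols, positions and biotypes came from GENCODE M21 on mm10, which names 54723 of the identifiers and places 54809. The other 115 identifiers have no symbol. Because the strand setting is unknown, values of antisense genes, pseudogenes and near-identical copies are uncertain.

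Counts were fitted in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the 4 groups, which left 15572, and libraries were scaled by trimmed mean of M values (TMM). A negative binomial model with 1 term per group was fitted over all 8 libraries, with 4 residual degrees of freedom, 6.3 prior degrees of freedom and a common biological coefficient of variation of 0.507. Each of 5 contrasts was tested with the quasi-likelihood F-test, which is two-sided: knockout against control at GV and at MII, MII against GV in control and in knockout oocytes, and the difference of the knockout effect between MII and GV. P-values were adjusted by the Benjamini-Hochberg method within each contrast, and a gene passed at an adjusted p below 0.05. The standard error (SE) of a log2 fold change is its size divided by the square root of F. CPM are read counts normalised to depth; those of single genes are relative to the reads in the tested genes and scaled by TMM. Summed CPM of gene lists and markers are relative to the reads in all genes, without scaling. Where all libraries of a group held 0 reads of a gene, the fold is a lower bound against a floor of 3 counts per library, and no fitted fold is given. Floors cover counting error only. Folds for groups with some reads but a mean below the floor, such as Gsto2 in control GV and Lrrc36 in knockout MII, are fitted values of uncertain size.

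Depth ranged from 19587421 to 33289150 reads in genes per library, so the floor of 3 counts lay between 0.0894 and 0.17 CPM. Counts were simulated with the same depths and spread, 1 baseline over all libraries and 200 changed genes. The changed genes were drawn from those with a mean of at least 5 CPM, so recovery of lower genes is not covered. The GV contrast recovered 4.48%, 47.8% and 98.5% of genes changed by log2 1, 2 and 4. The shares were 2.99%, 50.7% and 98.5% at MII and 0%, 16.4% and 78.8% for the difference between stages. For maturation in control oocytes the simulated counts gave 0%, 53.7% and 98.5%, and in knockout oocytes 4.48%, 59.7% and 98.5%. With so few changed genes, these shares do not describe the real maturation contrasts, which had 7649 and 7627 calls. Between 3.08% and 5.66% of simulated calls were unchanged genes.

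A set of 30 gene lists was fixed before the data were examined, as were the tests, the rule for named genes and the alternatives, except where stated. It comprises 25 functional lists and 5 lists of markers of other cell types, with 984 symbols of which 938 are in the table. The functional lists cover BAF subunits, oocyte transcription factors, zona pellucida and oocyte-secreted factors, maternal-effect genes, meiotic maturation kinases, spindle and kinetochore, cohesin and meiotic chromosome axis, and meiotic recombination. They further cover maternal mRNA storage and clearance, cytoplasmic ribosomal proteins, nuclear-encoded oxidative phosphorylation, mitochondrially encoded mRNAs, proteasome, DNA methylation, histone modifiers, other chromatin remodellers, piRNA and retrotransposon defence, and 2-cell embryo genes. The remaining ones are egg activation, p53 and DNA damage, oxidative stress defence, unfolded protein and heat shock response, cholesterol synthesis, imprinted genes and replication-dependent histones. The marker lists cover granulosa and cumulus cells, theca and stroma, endothelium, blood and immune cells, and ovarian surface epithelium. Lists with at least 3 tested members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the lists of a contrast. Camera with an estimated correlation and fry, which asks whether the genes of a list move on balance one way, were alternatives. With an estimated correlation, camera tests on the 4 residual degrees of freedom and so has little power here. Every list that passed with the preset lost its call in this way, so such a loss alone does not show that a list fails. The estimated correlation was, however, 0.611 for ribosomal protein genes and 0.832 for mitochondrially encoded mRNAs, far above the preset 0.01. For both lists the preset understates how far the members move together, so their p-values with the preset are likely too small. A first run applied camera by mistake to normal scores of the counts. It was replaced by the planned log2 CPM and kept as an alternative chosen after its result was seen. On simulated counts the list test called a shifted list of 40 genes and did not call an unshifted one.

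Genes are named by this rule: adjusted p below 0.05, a mean of at least 5 CPM in the higher group and, between 2 groups, all libraries of one group above the other, leaving out unnamed gene models and pseudogenes. The 8 largest rises and 8 largest falls of a contrast were taken. Arid1a, Arid1b and Smarca4 were always taken, as were up to 4 members with the smallest unadjusted p of each functional list with a called member or a passing camera test. A subset of these is printed, and 2 called genes are not reported here. Genes printed outside the rule (Rps3a2, Rps3a3, Epcam, Has2, Serpine2, Cdh1, Rbm28, Gm12463 and Gm8730) were chosen after their values were seen.

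Alternatives were RLE, upper-quartile and no scaling factors, the DESeq2 1.42.0 Wald test, limma-voom, no low-count filter, a mean of at least 5 CPM, only the libraries of the groups compared, the replicate number as a block, an added log2 fold change of at least 1, and leaving out each library in turn. Protein-coding genes alone were added after the data were seen. Sequence copies were sought with BLAST+ 2.17.0, and exact tests used SciPy 1.17.1 in Python 3.11.15.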

Results

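Gene-level read counts were available for 2 libraries each of control GV, knockout GV, control MII and knockout MII oocytes. Reads in genes numbered 20913886 and 19587421 in control GV, 22686587 and 22388567 in knockout GV, 26005880 and 29740748 in control MII (libraries a and b), and 33289150 and 28846136 in knockout MII. Replicates correlated across genes at 0.96 in control GV, 0.962 in knockout GV, 0.926 in control MII and 0.936 in knockout MII (log2 CPM). The first dimension of a multidimensional scaling held 53.8% of the variance and the second 15%. The share of reads on mitochondrial genes was 0.4461% and 0.1052% in control GV, 0.2489% and 0.3791% in knockout GV, 6.03% and 6.931% in control MII, and 3.029% and 4.408% in knockout MII. Group values below are means ± SD of 2 libraries, and log2 fold changes are given ± SE.

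The knockout was made to remove BAF250a from growing oocytes, and its gene, Arid1a (ENSMUSG00000007880, mm10 chromosome 4, 133679008 to 133756769, minus strand), was read first in every library. Arid1a held 8178 and 10928 reads in control GV and 86 and 312 in knockout GV. At MII it held 42047 and 39148 reads in control and 1109 and 576 in knockout libraries. Arid1a fell from 419 ± 55.4 to 8.88 ± 5.67 CPM at GV (log2 fold change -5.55 ± 0.50, adjusted p = 0.000526) and from 1455 ± 229 to 27.4 ± 7.98 CPM at MII (-5.73 ± 0.50, adjusted p = 0.000463). The remaining levels were 2.12% and 1.88% of control. Which exon was floxed is not given in the sources used here, so reads outside the deleted part are counted too. Arid1b, the alternative ARID1 subunit of the complex, was at 133 ± 13.1 CPM in control and 160 ± 8.42 CPM in knockout GV oocytes (0.27 ± 0.25, adjusted p = 0.85). At MII it was at 63.1 ± 3.52 and 32.2 ± 3.44 CPM (-0.97 ± 0.25, adjusted p = 0.0554). Smarca4, an ATPase of the complex, differed by -0.05 ± 0.32 at GV and -0.15 ± 0.32 at MII and passed at neither stage.

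**Figure D1:**
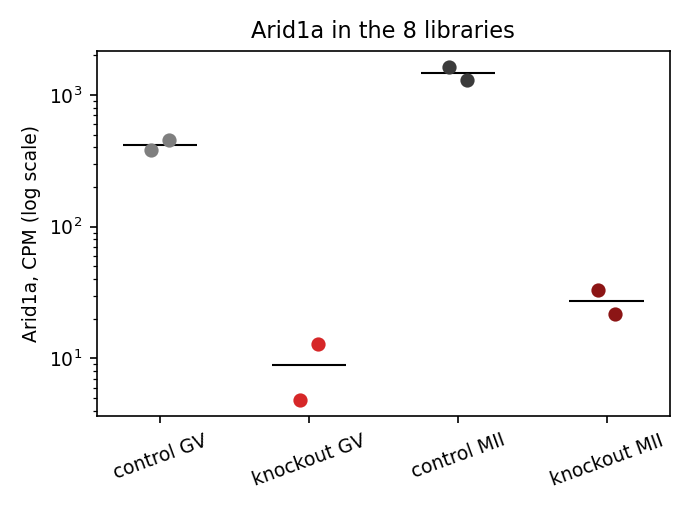
Arid1a in CPM (log axis) in each of the 8 libraries, as points by group, with a line at the group mean. Knockout libraries lay between 4.87 and 33 CPM and control MII libraries at 1617 and 1293 CPM.

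The first comparison asked which transcripts differ between knockout and control oocytes before meiosis resumes. Among the largest rises at GV were Gsto2, a glutathione transferase, and Pxdn, a peroxidase that cross-links collagen IV. Gsto2 rose from 0.0674 ± 0.036 to 74.2 ± 30.6 CPM (10.03 ± 0.67, adjusted p = 0.000136) and Pxdn from 0.323 ± 0.195 to 102 ± 31.4 CPM (8.26 ± 0.54, adjusted p = 0.000136). Bfsp1, a filament protein of the lens, had 0 reads in both control GV libraries and 196 ± 162 CPM in knockout GV, at least 1483-fold higher. Prr15l rose to 37.1 ± 6.58 CPM, Cap1, an actin regulator, to 8.34 ± 0.866 CPM and Rassf4 to 11.4 ± 2.21 CPM. Spesp1, a sperm equatorial segment protein, and the zinc finger gene Zfp990 were at least 43.8-fold and 42.6-fold higher. Among the falls, Dhrs3, a retinaldehyde reductase, fell from 34.6 ± 7.02 to 0.299 ± 0.103 CPM (-6.81 ± 0.63), and Cachd1 from 45.3 ± 1.71 to 0.956 ± 0.651 CPM (-5.59 ± 0.55). Extl1, a glycosyltransferase of heparan sulfate synthesis, changed by -8.00 ± 0.91 and the zinc transporter Slc30a2 by -6.16 ± 1.04. Adgrb1, an adhesion receptor, Colgalt2, a collagen galactosyltransferase, and Pnmt, which makes adrenaline, had 0 reads in knockout GV and were at least 78.6-fold, 49.7-fold and 38.4-fold lower.

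Of 15572 genes tested, 93 were higher and 61 lower in knockout GV oocytes (edgeR quasi-likelihood, n = 2 per group), and 1687 had an unadjusted p below 0.05. Of the called genes, 65 and 58 were protein-coding, and the median absolute log2 fold change of the calls was 3.26. The higher share of the calls was 60.4%, and 48.8% with library totals as the only scaling, which shifted the median of all genes by -0.27. Of the 21 named genes called, 9 kept the call whichever library was left out, among them Bfsp1, Prr15l, Gsto2, Pxdn, Adgrb1, Dhrs3, Cachd1 and Arid1a. The counts were 13 higher and 13 lower without control GV library 1, 15 and 14 without control GV library 2, 23 and 21 without knockout GV library 1, and 43 and 16 without knockout GV library 2.

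Few members of the functional lists passed at GV. Ect2, a regulator of cytokinesis, rose from 4.84 ± 0.211 to 23.1 ± 0.834 CPM (2.26 ± 0.34, adjusted p = 0.0125), the only call among 46 spindle and kinetochore genes, or 2 when adjusted over the list alone. Ndc80, of the outer kinetochore, was at 85.4 ± 5.07 and 196 ± 69.2 CPM (1.20 ± 0.29, adjusted p = 0.107). Plk4, the kinase of centriole duplication, rose from 22.0 ± 2.46 to 59.9 ± 0.59 CPM (1.45 ± 0.27, adjusted p = 0.0363), the only one of 38 meiotic maturation kinases and regulators to pass over all genes. Adjusted over the list alone, 1 was higher and 1 lower. Mapk3 was at 1482 ± 165 and 526 ± 57.3 CPM (-1.50 ± 0.35, adjusted p = 0.0984). Hormad1, of the meiotic chromosome axis, had 0 reads in control GV and 2.26 ± 1.19 CPM in knockout GV, at least 17.0-fold higher. It was the only call among 31 cohesin and axis genes, or 4 higher when adjusted over the list alone. Rps3a1 fell from 122 ± 22.0 to 21.4 ± 7.54 CPM (-2.51 ± 0.36, adjusted p = 0.00981), the only call among 78 ribosomal protein genes over all genes and when adjusted over the list alone. The processed pseudogenes Rps3a2 and Rps3a3, chosen after their values were seen, were higher at GV (5.70 and 6.65) and at MII (4.64 and 4.71). The median of the ribosomal list was -0.11 (camera adjusted p = 0.377).

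As sets, several lists had medians above 0 at GV with a preset correlation. The medians were 0.38 for spindle genes (camera adjusted p = 0.0106), 0.39 for cohesin genes (0.0106), 0.41 for 30 maternal-effect genes (0.0232), 0.37 for 21 recombination genes (0.0232), 0.31 for 50 mRNA storage genes (0.0232) and 0.36 for 48 histone modifiers (0.0337). None passed camera with an estimated correlation: the adjusted p = 0.455 for spindle genes, 0.501 for maternal-effect genes and 0.371 for the other lists. That correlation was -0.0161 for recombination genes and -0.00425 for histone modifiers, below the preset 0.01. For recombination genes and histone modifiers, a higher correlation was therefore not what cost the call. The estimate lay above the preset for spindle (0.0618), cohesin (0.0369), maternal-effect (0.0958) and mRNA storage genes (0.0165). No single maternal-effect, recombination, storage or histone modifier gene passed, over all genes or adjusted over the list alone. Nlrp9b was at 623 ± 71.1 and 1421 ± 166 CPM (1.19 ± 0.30, adjusted p = 0.113), and Kdm6a, a histone demethylase, at 14.6 ± 3.02 and 30.6 ± 1.60 CPM (1.06 ± 0.30, adjusted p = 0.176). Each of these lists lost its call with library totals as the only scaling and with a mean of at least 5 CPM. Without control GV library 1 all but the spindle list did, and without knockout GV library 1 all but the cohesin list; the histone modifier list also did without knockout GV library 2. Markers of granulosa and cumulus cells moved the other way, with a median of -0.73 over 24 tested (camera adjusted p = 0.0106, adjusted p = 0.371 with an estimated correlation, no call). They also lost it without control GV library 1.

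The second comparison asked the same of oocytes arrested at MII. Cytoplasmic ribosomal protein genes were the group with most calls: 34 of 78 fell, and 51 when adjusted over the list alone, and none rose. Rpl3 fell from 14.2 ± 2.98 to 0.214 ± 0.035 CPM (-6.01 ± 0.40, adjusted p = 0.000139), Rps4x from 27.1 ± 0.637 to 2.90 ± 0.0123 CPM (-3.22 ± 0.35, adjusted p = 0.00122) and Rps3a1 from 41.8 ± 11.1 to 3.4 ± 0.327 CPM (-3.62 ± 0.38, adjusted p = 0.00117). The list median was -1.71 (camera adjusted p = 5.42e-15, adjusted p = 0.85 with an estimated correlation). That correlation was 0.611, far above the preset 0.01, so the smaller p-value overstates the evidence. Summed over the list, ribosomal protein genes held 3227 and 3547 CPM in control MII and 2354 and 1475 CPM in knockout MII. Of 75 nuclear-encoded oxidative phosphorylation genes, 6 fell, also when adjusted over the list alone, with a list median of -0.39 (camera adjusted p = 0.0748). Over the list, their levels summed to 2670 and 2910 CPM in control MII and to 3200 and 2860 CPM in knockout MII. Ndufb7, of complex I, changed by -4.90 ± 0.68, Atp5d, of ATP synthase, by -3.95 ± 0.64 and Cox7c, of complex IV, by -2.25 ± 0.38. Ndufs8 had 0 reads in knockout MII, at least 22.8-fold lower. All 13 mitochondrially encoded mRNAs had negative fold changes, with a median of -1.13 (camera adjusted p = 0.0278, adjusted p = 0.85 with an estimated correlation), and no member passed. The last call was also lost without either control MII library and without knockout MII library 1.

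Single genes with the largest rises at MII included Slc27a2, a fatty acid transporter, which had 0 reads in control and 12.3 ± 6.04 CPM in knockout MII, at least 115-fold higher. Zfp990 and Prr15l were at least 61.9-fold and 57.8-fold higher. Pak3, a kinase acting on the actin cytoskeleton, rose from 0.132 ± 0.187 to 32.1 ± 4.85 CPM (7.81 ± 1.54, adjusted p = 0.0201). Bfsp1 rose to 15.7 ± 4.15 CPM (7.37 ± 0.98), Gsto2 to 23.3 ± 7.58 CPM (6.63 ± 0.56), Rassf4 to 9.50 ± 0.252 CPM (6.70 ± 1.05) and Pik3c2g to 6.66 ± 0.396 CPM (5.96 ± 1.45). The 8 largest falls were all to 0 reads in knockout MII. Cd300c, a receptor of myeloid cells, was at 37.7 ± 10.9 CPM in control (at least 372-fold lower), Odr4 at 21.5 ± 5.31 CPM (212-fold) and Timp1, an inhibitor of metalloproteinases, at 16.2 ± 1.39 CPM (160-fold). The others were the class I histocompatibility gene H2-D1 (at least 114-fold), the procollagen proteinase Bmp1 (89.2-fold), the collagen Col18a1 (72.4-fold), the lymphocyte antigen Cd52 (70.1-fold) and the chemokine Ccl3 (65.2-fold). The bound of H2-D1 rested mostly on control MII library b, at 21.3 CPM against 2.31 CPM in library a (relative to the reads in all genes, without scaling). Beside these falls, markers of granulosa and cumulus cells had a median of -2.27 over 24 tested, or -1.97 with groups at 0 reads set to the floor (camera adjusted p = 0.0112, adjusted p = 0.85 with an estimated correlation). Of them, 2 fell, and 10 when adjusted over the list alone; the list lost its call without control MII library b. Markers of blood and immune cells summed to 4.08 and 53.6 CPM in control MII and 4.54 and 3.74 CPM in knockout MII.

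In all, 265 genes were higher and 535 lower in knockout MII oocytes (n = 2 per group), of which 207 and 496 were protein-coding, and 3450 had an unadjusted p below 0.05. The median absolute log2 fold change of the calls was 3.59. Of the 49 named genes called, 25 kept the call whichever library was left out, among them Arid1a, Rpl3, Rps3a1, Rps4x, Ndufb7, Gsto2, Cd300c and Bmp1. The counts moved most without knockout GV library 1, to 123 higher and 242 lower, followed by 131 and 283 without knockout GV library 2, 145 and 270 without control GV library 2, and 148 and 270 without control GV library 1. Without control MII library a 146 were higher, and without knockout MII library 2 291 were lower.

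Genes of the meiotic spindle went both ways at MII. Nusap1, a microtubule-bundling protein, rose from 14.9 ± 11.8 to 149 ± 6.6 CPM (3.33 ± 0.51, adjusted p = 0.00756), Spc25, of the NDC80 complex, from 15.5 ± 5.55 to 95.8 ± 55.8 CPM (2.63 ± 0.47, adjusted p = 0.0139) and Tubg1, γ-tubulin, from 28.1 ± 9.07 to 107 ± 28.1 CPM (1.92 ± 0.34, adjusted p = 0.0121). Tacc3, which stabilises spindle microtubules, fell from 7.43 ± 0.56 to 1.84 ± 0.871 CPM (-2.03 ± 0.40, adjusted p = 0.0204). In all, 4 of 46 rose and 1 fell, and 4 and 2 when adjusted over the list alone. Hormad1 was again higher, from 0.165 ± 0.0931 to 8.73 ± 2.12 CPM (5.70 ± 1.00), the only call among 31 cohesin and axis genes, or 2 when adjusted over the list alone. The cohesin list had a median of 0.29 (camera adjusted p = 0.0167, adjusted p = 0.85 with an estimated correlation). Esco2, a cohesin acetyltransferase, was at 97.1 ± 25.1 and 230 ± 7.08 CPM (1.24 ± 0.32, adjusted p = 0.0522).

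Calls among oxidative stress and unfolded protein genes at MII went both ways, and neither list passed the main test (camera adjusted p = 0.135 and 0.866). The alternative fry called the oxidative stress list lower (fry adjusted p = 0.0381) and did not call the unfolded protein list (0.353). Of 29 oxidative stress genes, 1 rose and 3 fell, and 2 and 5 when adjusted over the list alone. Gss, of glutathione synthesis, and Gstm2, a glutathione transferase, had 0 reads in knockout MII (at least 9.80-fold and 13.2-fold lower), and Prdx4 changed by -6.20 ± 1.14. Prdx2, a peroxiredoxin, rose from 286 ± 8.10 to 1118 ± 346 CPM (1.97 ± 0.42). Of 30 unfolded protein and heat shock genes, 1 rose and 2 fell, and 3 and 6 when adjusted over the list alone. Xbp1, a transcription factor of this response, changed by -7.15 ± 1.23, while the chaperone Hspd1 rose from 58.2 ± 4.58 to 138 ± 32.1 CPM (1.25 ± 0.30). Among 48 histone modifiers, the deacetylase Sirt1 rose from 5.37 ± 1.18 to 32.4 ± 9.66 CPM (2.59 ± 0.54), and the arginine methyltransferase Prmt5 fell from 123 ± 2.60 to 52.2 ± 1.87 CPM (-1.24 ± 0.26). Both were called over all genes and adjusted over the list alone. Of the genes in this paragraph, Gss and Xbp1 kept the call whichever library was left out. Gstm2, Prdx4, Prdx2, Hspd1, Sirt1 and Prmt5 did not.

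Other calls in lists at MII were single genes. Ctsl, a cathepsin, fell from 28.2 ± 7.83 to 0.395 ± 0.452 CPM (-6.09 ± 0.86), and Figla, a transcription factor of zona genes, changed by -3.15 ± 0.79. Cd9, needed on the egg surface for sperm fusion, changed by -1.77 ± 0.37 and Tdrd5, of the piRNA pathway, by -1.32 ± 0.31. Each was the only call of its list, over all genes and adjusted over the list alone. Among 21 recombination genes Ccnb1ip1 was at least 42.4-fold higher and Psmc3ip changed by -5.08 ± 1.09, 1 up and 1 down by either adjustment. Of 50 mRNA storage and clearance genes, Edc3 and Cnot10 fell over all genes and none adjusted over the list alone. Pmvk, of cholesterol synthesis, and the histone gene Hist1h4i had 0 reads in knockout MII (at least 15.1-fold and 19.7-fold lower), the only calls among 22 and 19 genes, also when adjusted over the list alone. Of 26 BAF subunits, Arid1a fell at both stages, and at MII 2 fell when adjusted over the list alone. No camera test of these lists passed at MII, while fry called the cholesterol synthesis list lower (fry adjusted p = 0.0381). Of the single genes, Arid1a, Ctsl, Ccnb1ip1 and Hist1h4i kept the call whichever library was left out. Figla, Cd9, Tdrd5, Psmc3ip, Edc3, Cnot10 and Pmvk did not.

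A further question was whether the same genes differed at both stages. The 2 comparisons share no library but share the spread of each gene, estimated over all 8 libraries. Of the GV calls, 91.6% had the same sign at MII, and of the MII calls, 79.6% had the same sign at GV. Called in both, 53 genes were higher and 39 lower, and 1 gene was called in opposite directions. Independent calls would give 1.58 and 2.1. The shared spread makes calls at both stages more likely, so these are not a strict chance level. Across the 15572 genes the effects correlated at 0.354 (Pearson) and 0.322 (Spearman), with the caution that genes are not independent replicates. Higher at both were Gsto2, Bfsp1, Prr15l, Zfp990, Rassf4 and Hormad1, and lower at both Dhrs3, Cachd1, Extl1 and Rps3a1. Of these, Hormad1, Zfp990 and Rps3a1 have 2, 15 and 7 near-identical copies elsewhere, so shared reads were not excluded for them. None was found for the others. Of the 53 rises, 39.6% were pseudogenes, against 5.47% of tested genes. Besides Arid1a, 16 of the 91 other genes called in the same direction lay on chromosome 4, among them Zfp990, Cap1, Dhrs3, Cachd1, Extl1 and Slc30a2. The counts fell to 11 higher and 12 lower without control GV library 1, 13 and 12 without control GV library 2, 20 and 12 without knockout GV library 1, and 28 and 15 without knockout GV library 2.

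**Figure D2:**
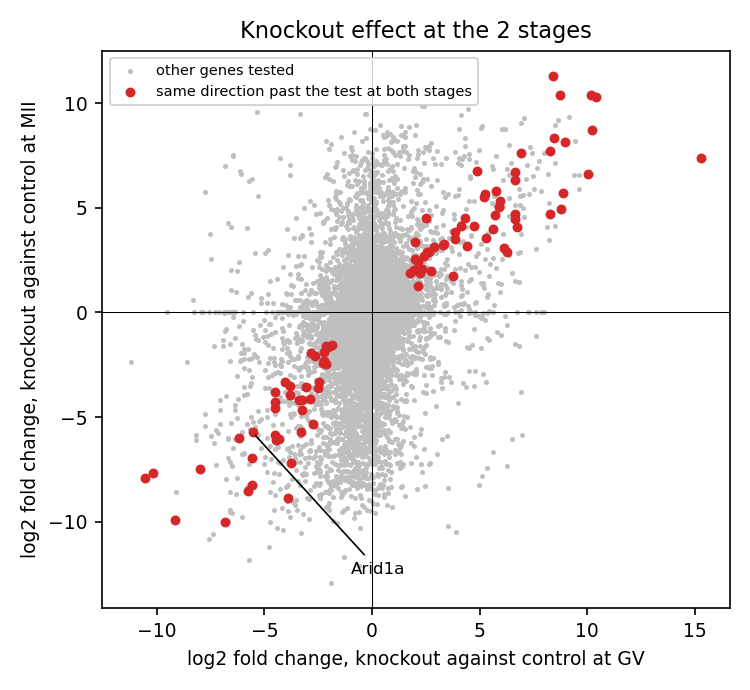
Log2 fold change of knockout against control at GV (x axis) and at MII (y axis) for the 15572 genes tested, 1 point per gene. Red points are the 53 and 39 genes called in the same direction at both stages, with Arid1a at -5.55 and -5.73.

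**Figure D3:**
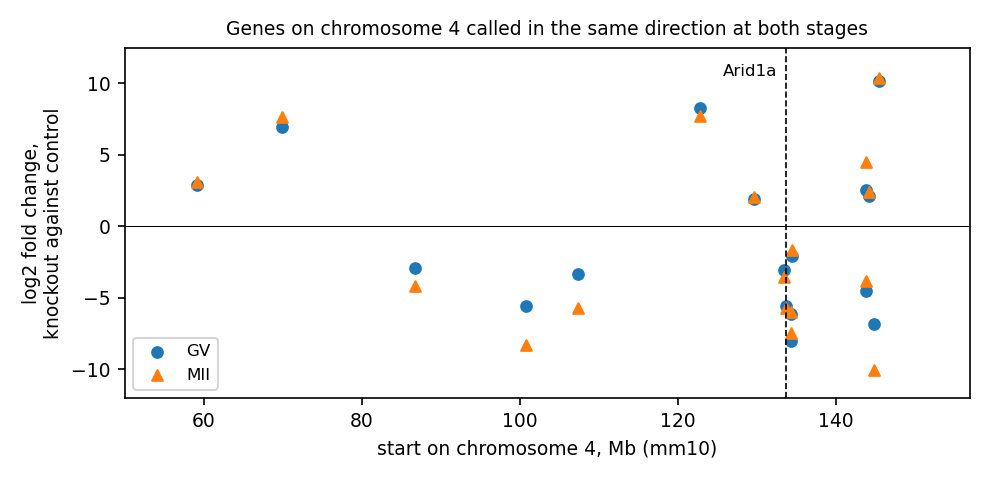
Log2 fold change of knockout against control at GV (circles) and MII (triangles) for Arid1a and the 16 other genes of chromosome 4 called in the same direction at both stages, by start position in Mb (mm10). The dashed line marks Arid1a.

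The difference of the knockout effect between MII and GV was tested directly. Vps39, a subunit of the endolysosomal HOPS complex, had the only positive difference (3.13 ± 0.44, adjusted p = 0.0458). It was at 121 ± 19.5 and 80.3 ± 15.2 CPM in control and knockout GV, and at 33.4 ± 0.79 and 195 ± 63.9 CPM in control and knockout MII. Rpl3 had the smallest adjusted p among the 12 negative differences (-5.01 ± 0.48, adjusted p = 0.0142), and Rps4x also passed (-3.30 ± 0.46, adjusted p = 0.0458). Mbl2, a lectin of complement activation, was at 345 ± 42.4 and 132 ± 14.7 CPM at GV and 58.3 ± 25.1 and 1.90 ± 0.342 CPM at MII (-3.54 ± 0.48). Got1, an aspartate aminotransferase, was at 33.3 ± 10.3 and 59.2 ± 2.80 CPM at GV and 50.7 ± 0.385 and 7.08 ± 2.00 CPM at MII (-3.67 ± 0.49). Ribosomal protein genes had a median difference of -1.54 (camera adjusted p = 1.76e-12, adjusted p = 0.795 with an estimated correlation), with 2 of 78 lower, or 36 adjusted over the list alone. Mitochondrially encoded mRNAs had a median difference of -1.08 (camera adjusted p = 0.0117, adjusted p = 0.795 with an estimated correlation, no member called), a call lost without control GV library 2, control MII library b, knockout GV library 2 or knockout MII library 1. No other list passed, and 1787 genes had an unadjusted p below 0.05.

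The calls of the difference depended on the setting. With RLE or upper-quartile scaling 1 negative call was left, and with limma-voom 0 calls were left (1730 genes with unadjusted p below 0.05), whereas DESeq2 called 111 higher and 244 lower. None of the 9 named genes kept its call in all leave-one-out fits: 9 lost it without each of control GV libraries 1 and 2, control MII library a, knockout GV libraries 1 and 2 and knockout MII library 2, and 6 without control MII library b or knockout MII library 1.

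Maturation from GV to MII was compared within each genotype. CPM are relative levels and no measure of RNA per oocyte was used. Rises and falls between stages are therefore relative to the other transcripts and not changes in amount per oocyte. In control oocytes Zp3, a zona pellucida glycoprotein, fell from 4959 ± 209 to 198 ± 19.4 CPM (-4.65 ± 0.37, adjusted p = 1.84e-05) and Nobox, a transcription factor of oocyte genes, from 949 ± 276 to 32.2 ± 7.08 CPM (-4.88 ± 0.37, adjusted p = 1.49e-05). In knockout oocytes Zp3 changed by -3.98 ± 0.36 and Nobox by -4.35 ± 0.36. Ribosomal protein genes fell in 74 of 78 cases in control (median -3.57) and 72 in knockout oocytes (median -5.09), with 2 higher in each. Oxidative phosphorylation genes fell in 58 of 75 cases in both (medians -2.90 and -3.54), with 3 and 4 higher. Mitochondrially encoded mRNAs rose in 13 of 13 cases in control (median 5.00) and 12 in knockout oocytes (median 4.20). Mt-Co2 rose from 1.77 ± 0.844 to 85.7 ± 4.10 CPM in control (5.60 ± 0.49) and from 2.26 ± 0.331 to 41.6 ± 15.9 CPM in knockout oocytes (4.20 ± 0.46). Proteasome genes fell in 20 and 22 of 31 cases (medians -2.04 and -2.71). Adjusted over the list alone, the falls were 75 and 74 of ribosomal protein, 63 and 59 of oxidative phosphorylation and 20 and 23 of proteasome genes, and 13 mitochondrial mRNAs rose in each.

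**Figure D4:**
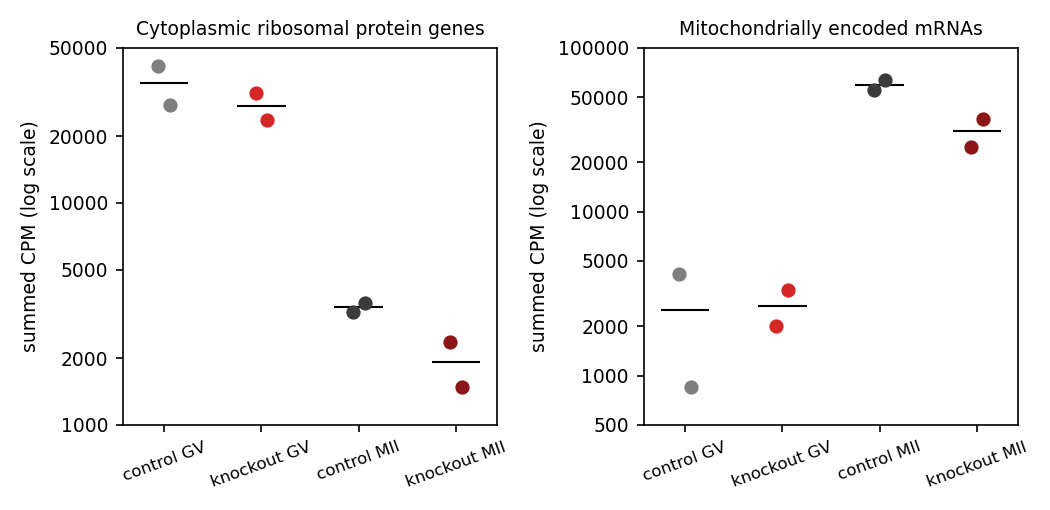
Summed CPM (log axis) of cytoplasmic ribosomal protein genes and of mitochondrially encoded mRNAs in each of the 8 libraries, as points by group with a line at the group mean. Ribosomal protein sums ran from 41584 CPM in a control GV library to 1475 CPM in a knockout MII library, and mitochondrial sums from 853 CPM to 63895 CPM.

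In control oocytes 3302 genes rose and 4347 fell, and in knockout oocytes 3102 rose and 4525 fell. The excess of falls depended on scaling: with upper-quartile factors 3909 rose and 3944 fell in control oocytes, and 3732 and 4067 in knockout oocytes. Without knockout GV library 1, 2064 rose in knockout oocytes. Both genotypes shared 2553 rises and 3478 falls (657.8 and 1263 if calls were independent, although the spread is shared). In the genotypes 11 genes were opposite, and the changes correlated across genes at 0.7328 (Pearson) and 0.7863 (Spearman). Camera adjusted p-values with a preset correlation were 9.1e-13 and 1.23e-16 for ribosomal protein genes and 3.13e-09 and 1.73e-09 for oxidative phosphorylation. They were 2.42e-07 and 5.03e-06 for mitochondrial mRNAs and 0.00278 and 0.000537 for the proteasome. For ribosomal protein genes the adjusted p = 0.526 with an estimated correlation in control and 0.459 in knockout oocytes, and the other 3 lists gave 0.448 to 0.526 in control and 0.459 in knockout oocytes. The median of all genes was -0.20 in control oocytes, 0.04 with upper-quartile, -0.33 with RLE and -0.36 without scaling factors. In knockout oocytes it was -0.33, -0.04 with upper-quartile and -0.40 with RLE scaling, and the directions of these 4 lists held under each.

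The largest single rises in control oocytes were of genes hardly seen at GV. Spp1, osteopontin, rose from 0.299 ± 0.364 to 191 ± 52.1 CPM (9.34 ± 1.21, adjusted p = 0.000186), and Nupr1, a stress-response gene, from 0.69 ± 0.206 to 72.1 ± 17.5 CPM (6.70 ± 1.42). Cd52, Lox, a collagen cross-linking enzyme, and Vegfa, a vascular growth factor, were at least 53.6-fold, 53.4-fold and 43.6-fold higher. In knockout MII oocytes Spp1 was at 0.857 ± 1.11 CPM and Nupr1 at 2.17 ± 3.08 CPM. Granulosa and cumulus markers with at most 5 CPM in every GV library summed to 39.2 and 80.3 CPM in control MII and to 10.2 and 3.05 CPM in knockout MII. All 34 markers in the table summed to 540 and 612 CPM in control MII and 587 and 456 CPM in knockout MII. The largest falls in control oocytes included Best2 (at least 173-fold) and Spa17 (at least 146-fold). In knockout oocytes Tox3 rose from 0.693 ± 0.863 to 21.3 ± 2.62 CPM (5.01 ± 0.90) and Rhobtb3 from 0.616 ± 0.17 to 15.2 ± 3.50 CPM (4.62 ± 0.77). Prss12, a serine protease, was at least 658-fold lower. Lrrc36 fell from 184 ± 73.6 to 0.0338 ± 0.00563 CPM, below the floor of 3 counts, so its fitted change (-12.23 ± 0.58) is of uncertain size.

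Chromatin regulators differed in direction during maturation. Of 48 histone modifiers, 23 rose and 6 fell in control oocytes (median 0.74, camera adjusted p = 0.0108), and of 25 other remodellers 11 rose and 2 fell (median 0.94, camera adjusted p = 0.0108). For both the adjusted p = 0.448 with an estimated correlation, and the counts adjusted over the list alone were the same. Bmi1, a Polycomb subunit, rose from 87.2 ± 24.9 to 931 ± 78.8 CPM (3.42 ± 0.36), and Kat8, a histone acetyltransferase, fell from 350 ± 177 to 5.45 ± 1.45 CPM (-6.00 ± 0.50). In knockout oocytes 17 and 7 histone modifiers and 10 and 2 remodellers rose and fell (camera adjusted p = 0.108 and 0.0933). Cohesin and axis genes rose in 16 and fell in 7 of 31 cases in control (median 1.23, camera adjusted p = 0.0523) and in 14 and 6 in knockout oocytes (median 1.47, camera adjusted p = 0.0344, adjusted p = 0.459 with an estimated correlation). Adjusted over the list alone these were 16 and 9, and 15 and 6; the knockout call was lost without knockout MII library 1. Rad21, a cohesin subunit, rose from 14.8 ± 1.14 to 113 ± 14.8 CPM in control (2.93 ± 0.29) and changed by 2.05 ± 0.28 in knockout oocytes. Of 26 BAF subunits, 6 rose and 5 fell in control and 7 each in knockout oocytes, the same when adjusted over the list alone. Arid2 rose by 2.32 ± 0.26 and 2.14 ± 0.26, while Arid1b changed by -1.07 ± 0.25 and -2.31 ± 0.26. Arid1a itself changed by 1.80 ± 0.42 and 1.62 ± 0.43 on the log2 scale.

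To ask whether the relative composition of the transcript pool changed less or more during maturation of knockout oocytes, genes were grouped by their mean change over both genotypes. The 6587 genes that fell by more than log2 1 had medians of -3.06 in control and -3.47 in knockout oocytes, and a median difference of -0.13 relative to the median of all genes. The 4559 genes that rose by more than log2 1 had medians of 1.89 and 1.85 and a relative difference of 0.07. Both depended on single libraries: without knockout MII library 1 they were -0.42 and 0.27, and without control MII library b 0.13 and -0.05.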

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

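Of the tests in this part, those on RNA carried over from GV oocytes and on RNA of other cell types were chosen after their results were seen. The test of the difference between stages was planned, and the tests on length, expression and pseudogenes were written before their results.

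A difference of the knockout effect between GV and MII passed for 13 genes and 2 lists, by the test of the difference itself (log2, effect at MII minus effect at GV). The single positive difference was that of Vps39, 3.13. Genes of metabolism with a negative difference included Ptgr1 (-7.46) and Got1 (-3.67). Odr4 and Tep1 had 0 reads in knockout MII, and with that group set to the floor their differences were -7.10 and -4.41 or stronger. The lectin gene Mbl2 differed by -3.54, Mfap1b by -3.46 and the nucleolar protein gene Rbm28 by -3.26. The gene models Gm12463 and Gm8730 differed by -4.07 and -3.73. The ribosomal protein genes Rpl3 and Rps4x differed by -5.01 and -3.30. As a set, ribosomal protein genes differed by a median of -1.54 and mitochondrially encoded mRNAs by -1.08, with no member of the latter called. Both list calls were lost with an estimated correlation (adjusted p = 0.795 for each) and with fry (adjusted p = 0.328 and 0.4), and that of the mitochondrial mRNAs also with a mean of at least 5 CPM and without control GV library 2, control MII library b, knockout GV library 2 or knockout MII library 1. None of the 9 named genes kept its call without control GV library 1, control GV library 2, control MII library a, knockout GV library 1, knockout GV library 2 or knockout MII library 2. Ptgr1, Odr4, Tep1, Mbl2, Mfap1b, Got1, Vps39, Rpl3 and Rps4x are those 9, and others are given because the count is small.

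Ribosomal protein genes were lower in knockout than in control MII oocytes (median -1.71), a list call lost with an estimated correlation (adjusted p = 0.85) and with fry (adjusted p = 0.117) and kept in the other alternatives run. A trend with transcript length or expression level did not account for this, since the lowest median of 10000 lists matched on both was -0.34, nor did reads counted on pseudogenes instead, which would have raised these, while their summed level changed by -20.9 CPM beside -1473 CPM for the genes. Of 7236 genes with at least 10 CPM in control GV, 9.19% and 11% kept less than 0.5 times the share of the control GV level that ribosomal protein genes kept. This argues against RNA of GV oocytes as the source of all ribosomal protein RNA in the control MII libraries. It cannot exclude a smaller carry-over that accounts only for the excess over knockout. The cut of 0.5 also makes no allowance for low genes missed in small libraries. RNA of granulosa or cumulus cells in the control MII libraries is a candidate explanation: 26 markers with at most 5 CPM in every GV library, used after a choice by knockout level was dropped as circular, summed to 39.2 and 80.3 CPM in control MII and 10.2 and 3.05 CPM in knockout MII, an order also taken by the ribosomal protein sums (3227, 3547, 2354 and 1475 CPM), and 12 of 19 seen at MII were higher in both controls, though Has2 was not, and all 34 markers, Serpine2 the most abundant, summed to 540 and 612 CPM in control MII and 587 and 456 CPM in knockout MII, without that order. The same 26 markers were also higher in control GV (24.3 and 22.3 CPM) than in knockout GV (8.82 and 8.58 CPM), where the ribosomal median was -0.11. Of 3302 genes that rose in control maturation, 74 were lower in knockout MII, below the 113 if calls were independent. RNA of other cells in control MII would tend to raise this overlap, so it does not favour that explanation, without excluding it. RNA of blood or immune cells cannot be told apart from RNA of granulosa or cumulus cells. Its markers summed to 4.08 and 53.6 CPM in control and 4.54 and 3.74 CPM in knockout MII, with 4 and 7 of 21 above both knockout libraries. A stronger loss of ribosomal protein transcripts in oocytes without BAF250a stayed open and untested, as did a difference in poly(A) length or library chemistry.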

How the results depend on the processing

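All alternatives here were planned except protein-coding genes alone and camera on normal scores of the counts, which were added after the data were seen. The cause was not tested for any changed result below, unless stated. In fits without 1 library, the lone library of its group is assumed to vary like the others.

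At GV, 93 higher genes became 59 with library totals only, 304 with DESeq2, 336 with no low-count filter and 372 with only the 4 libraries compared, and 61 lower genes became 222 with DESeq2, 191 with no filter and 396 with only the 4 libraries. At MII, 265 higher genes became 651 with DESeq2 and 599 with no filter, and 535 lower genes 1122 and 1230. With only the 4 MII libraries, 347 were higher and 422 lower, so 45.1% of the calls were higher against 33.1% in the main test. That fit shared 464 of the 800 main calls, and the fit on the 4 GV libraries shared 153 of 154. DESeq2 called all 154 GV genes again and 794 of the 800 MII genes. Limma-voom called 127 and 69 genes at GV and 397 and 624 at MII, sharing 124 of the 154 GV calls and 589 of the 800 MII calls. Protein-coding genes alone gave 68 and 60 at GV, 225 and 516 at MII and 1 and 13 for the difference between stages.

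Leaving out each library in turn gave 13 to 98 higher and 13 to 79 lower genes at GV, and 123 to 258 higher and 242 to 505 lower at MII. Control GV library 1 (13 and 13 at GV), control GV library 2 (15 and 14), knockout GV library 1 (23 and 21) and knockout GV library 2 (43 and 16) moved these counts most. At MII these 4 gave 148 and 270, 145 and 270, 123 and 242, and 131 and 283; control MII library a gave 146 higher and knockout MII library 2 gave 291 lower. In knockout maturation the rises ranged from 2064, without knockout GV library 1, to 3158, and no other maturation count moved by over 1.5 times. Genes shared by both stages numbered 11 to 51 higher and 12 to 44 lower, lowest without the GV libraries (11, 13, 20 and 28 higher and 12, 12, 12 and 15 lower, in the order above). The Pearson correlation of the effects, 0.35, ranged from 0.30 to 0.34 and was 0.48 with a mean of at least 5 CPM. The relative difference of genes that fell in maturation ranged from -0.42 without knockout MII library 1 to 0.13 without control MII library b, and that of genes that rose from 0.27 to -0.05 without the same libraries.

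For the difference between stages, 1 higher and 12 lower genes by edgeR became 0 and 1 with RLE or upper-quartile factors (1729 and 1752 genes with unadjusted p below 0.05), 0 and 2 with library totals (1574), 0 and 0 with limma-voom (1730), 111 and 244 with DESeq2, 125 and 373 with no filter and 5 and 36 with a mean of at least 5 CPM. Leaving out 1 library gave 0 to 2 higher and 0 to 18 lower genes. There were 0 of either without control GV library 1, control GV library 2, control MII library a, knockout GV library 2 and knockout MII library 2 (1487, 1169, 1815, 1365 and 1858 with unadjusted p below 0.05). Without knockout GV library 1 they were 0 and 1, without control MII library b 1 and 10, and without knockout MII library 1 2 and 18. Library totals shifted the median of all genes from -0.14 to 0.07.

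Signs changed only for genes not called. Arid1b at GV was -0.02 with library totals. Leaving out 1 library gave ranges across 0 for the rest: Smarca4 at GV from -0.11 to 0.02, the latter without control GV library 2, at MII from -0.47 to 0.40 and in control maturation from -0.33 to 0.53, the reversed end being without control MII library a in both. Its difference between stages ranged from -0.42 to 0.45 and was 0.11 with library totals, 0.45 without control MII library a and 0.03 without knockout MII library 2. Ring1 at MII ranged from -7.68 to 2.08, the latter without control MII library b. The Arid1a difference between stages ranged from -0.67 to 0.69 and was 0.02, 0.69 and 0.16 without control MII library a, knockout GV library 2 and knockout MII library 2.

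Over all named genes and alternatives, 6332 values stayed on their side of the threshold, 326 lost and 105 gained the call and 11 changed sign. For lists that passed, 295 values stayed and 77 lost the call: all lost it with an estimated correlation, and with a mean of at least 5 CPM so did all GV lists, the cohesin, granulosa and mitochondrial lists at MII, remodellers in control and cohesin genes in knockout maturation, and the mitochondrial list in the difference between stages. With fry all GV lists, the cohesin, ribosomal and mitochondrial lists at MII and the last 2 in the difference lost it. Of the named genes called in the maturation of control and knockout oocytes, 108 and 112 of 117 kept the call in all leave-one-out fits. Deviations of same-numbered libraries correlated across genes at 0.119 between the GV groups, 0.0127 between control GV and knockout MII and -0.02 between the knockout groups. These values show no strong effect shared by number. With 2 libraries per group, they cannot tell whether same-numbered libraries share an animal or day. With the number as a block, GV gave 83 higher and 47 lower genes, sharing 115 calls, and knockout maturation 2959 and 4068; control MII has no numbers, so the block was not run for its comparisons. With the depth, spread and number of libraries here, the simulated GV contrast recovered 47.8% of changes of log2 2 and 4.48% of changes of log2 1. The changed genes of this simulation had a mean of at least 5 CPM.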

Other observations

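Of the tests in this part, those on chromosome segments and on pseudogene copies were chosen after the pattern was seen; the test on copies of other genes was written before its result.

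Of the functional lists, 8 held no gene that passed between genotypes at GV or MII over all genes. Among them were proteasome (31 tested, medians 0.14 and -0.25), maternal-effect genes (30 tested), other chromatin remodellers (25 tested, with 1 higher and 2 lower at MII when adjusted over the list alone) and mitochondrially encoded mRNAs (13 tested). The remaining 4 were DNA methylation (16 tested, median 0.04 at GV with a mean of -0.24, and 0.14 at MII with a mean of -0.26), 2-cell embryo genes (10 tested, 0.26 and -0.06), p53 and DNA damage (33 tested, -0.05 and -0.06) and imprinted genes (21 tested, 0.08 and 0.08). Some members of these 4 passed in maturation of control oocytes. Dnmt1, the maintenance methyltransferase, fell from 3111 ± 153 to 332 ± 113 CPM (-3.23 ± 0.38), with 3 of the DNA methylation genes higher and 6 lower. Of the 2-cell genes 5 fell, Arg2 from 62.5 ± 9.29 to 0.484 ± 0.404 CPM (-7.03 ± 0.56). Of the p53 and DNA damage genes 11 rose and 5 fell, with the checkpoint kinase Chek1 rising from 129 ± 14.8 to 576 ± 50.1 CPM (2.15 ± 0.26). Imprinted genes rose in 8 and fell in 3 cases, Grb10 by 1.34 ± 0.36 and Mest by -2.26 ± 0.58. Adjusted over the list alone, all of these counts were the same, and no camera test of these 4 lists passed between genotypes at GV or MII or in control maturation.

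Summed markers of other cell types were highest for granulosa and cumulus cells and for surface epithelium. The former reached 612 CPM in control MII library b (365 CPM of it Serpine2). The latter reached 503 CPM in knockout MII library 1 (412 CPM of it Cdh1). Serpine2 and Cdh1 were the most abundant markers of their lists in all 8 libraries, Cdh1 at 120 CPM or more. These sums alone therefore do not show that other cells were present. Endothelial markers (8 tested) had no call between genotypes, 1 higher at GV when adjusted over the list alone, and 3 rises at MII in control oocytes. Of 5 tested theca and stroma markers none differed between genotypes. Of 5 tested surface epithelium markers Epcam was higher at both stages (5.22 and 5.50), the only one called, or 2 higher and 1 lower at GV when adjusted over the list alone. Of 6 tested immune markers none passed between genotypes over all genes, and 4 were lower in knockout MII when adjusted over the list alone; 2 fell during maturation in each genotype over all genes.

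Of the 92 genes that moved the same way at both stages, an excess lay on the chromosome of the targeted gene. Besides Arid1a, 17.6% of them lay on chromosome 4 against 6.07% of other tested genes (odds ratio 3.3, Fisher's exact p = 0.00012, two-sided), 11 of them within 20 Mb of Arid1a. Those 11 include Zfp990, Cap1, Dhrs3, Extl1 and Slc30a2, named above among the largest changes. A candidate explanation, found from these same calls, is a segment around the targeted allele that differs in sequence from the control chromosome, although direct effects of BAF250a loss stay open and untested. Whether further segments contribute cannot be told apart from chance: off chromosome 4, 28% of the 75 genes had another within 1 Mb, against a median of 17.3% in draws from genes called at MII only (4.74% of draws as high) and of 10.7% in draws from all tested genes, and 7 of them lay between 93 and 96 Mb of chromosome 5. Among these 7, D5Ertd577e and Gm3106 are near-identical copies of each other, as are C87414, AA792892 and Gm3259. Such copies can share reads and are not separate evidence of a segment. On chromosome 4, Gm11223, Gm13103, Gm13100, C87977 and Zfp990 also have near-identical copies, and the exact test made no allowance for this. For most of the 71 genes that are not pseudogenes, no copy with 90% identity over 50% of a transcript was found. Shorter shared stretches and copies outside the annotation were not sought, so shared reads are not excluded for these genes. Reads shared with near-identical copies stay open for the 16 with such a copy, among them Hormad1, Zfp990 and Rps3a1. They also stay open for the 21 pseudogenes, all higher, of which 16 had one with enough reads, beside 70.3% of other tested pseudogenes (Fisher's exact p = 0.637).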
